A study of Mus musculus with 2 samples.

How the data were processed

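The study profiled molar epithelium and molar mesenchyme of Krt14-RFP mice with 10x Genomics droplet sequencing, with 1 library per tissue layer. Per the labels' protocols, molars of 7 littermates were dissected, digested with Dispase II, separated under a microscope, dissociated with Accutase and captured with a kit named as version 3, and the libraries were pooled and sequenced on 4 lanes. The labels state an age of postnatal day 1, whereas the protocol text names day 7 and in places incisors. The raw matrices list 737280 barcodes, and the genome build is not named by the labels or files.

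The authors deposited raw UMI counts per gene and barcode, once for all barcodes and once for barcodes called as cells, and no normalization is recorded. The counts were made with Cell Ranger 2.1.0, per the submitters' processing notes. The deposited count matrices hold 48816 features, of which 48709 carry mouse gene IDs and 107 are spike-in and transgene sequences. Of the mouse gene IDs, 41341 matched GENCODE M21 with the same version and 48349 without the version, so gene names were taken from the files and no positions are given. Symbols shared by more than 1 row (238 rows) were kept apart by ID.

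Barcodes were kept with at least 500 detected genes and at most 10% mitochondrial UMIs. This set aside 58 barcodes of the epithelium library and 164 of the mesenchyme library with fewer genes, whose UMIs were mostly globin (medians of 92.1% and 94.9%), and 11 and 8 barcodes with more mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.05. It marked 16 of 5962 barcodes (0.268%) in the epithelium library, which was under the 0.5% below which it was taken not to have worked, so none were removed there; 148 of 6009 were removed in the mesenchyme library. The kept barcodes held 38587957 and 37249350 UMIs.

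Each library was clustered alone: counts per 10000, log1p, 2000 variable genes, 30 components (scikit-learn 1.9.0), 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9), with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and Python 3.11.15. This gave 26 clusters in the epithelium library and 24 in the mesenchyme library. Transgene and spike-in features were not used. The markers of 15 broad classes and of the epithelial and mesenchymal subtypes were fixed before the data were examined, as were the gene lists, the comparisons and the main settings.

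The rule that turns marker levels into names was not fixed in full and was revised after the clusters had been seen, in 3 versions. In the first, marker CPM was scaled by the highest cluster, and a name required that no other class had more markers among the 10 leading genes over the rest of the library. In the second, markers were scored on a log scale with an offset of 10 CPM, a class needed at least 3 markers detected (20 CPM and 10% of barcodes), and leading genes were ranked over clusters of other classes in the same library. The third, which is used, ranks them over such clusters of both libraries and lets a subtype fall back on another with at least 2 of its markers among the leading genes. The third version was prompted in part by large Krt14-positive clusters that had stayed unnamed because of the neuron marker Stmn2, and it raised the epithelial share of the epithelium library from 73.1% to 84.3%. When leading genes are ranked over the rest of their own library, cluster 17 of the epithelium library (160 barcodes) and cluster 10 of the mesenchyme library (269 barcodes), both epithelial-like, carry more markers of another class, so epithelial-like shares are given per library and class-restricted counts are also given without cluster 17.

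UMIs were summed per library, class or subtype and scaled to CPM. Folds are ratios of CPM, and a sum of 0 was set to a floor of 3 counts. Where that floor would have reversed the direction no direction was given, a rule added after seeing the data. Such genes entered list medians with a log2 ratio of 0, as did genes with at most 3 counts in both sums. Sums carry exact Poisson intervals, ratios exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. With 1 library per group no test was run. A list's median log2 ratio over members with at least 10 UMIs was placed among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. The fold count was tested on simulated data: for the epithelium against the mesenchyme library over 48709 genes, 100 of 100 genes simulated at 8-fold, 0 of 100 at 2-fold and 0 of 18475 unchanged genes passed 4-fold. The simulated counts came from 1 shared profile with counting error only. They cannot tell how many genes would pass 4-fold between replicate libraries of 1 layer.

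Named genes are the 12 largest folds in each direction with at least 50 CPM in the higher library, up to 4 members of each list with the largest folds and at least 20 CPM, and Krt14, 113 genes in all. Other genes were singled out after their values were seen, among them Ambn, Sema3e, Col1a1 and the genes given per subtype. G2M UMIs were counted after each barcode was thinned to 3000 UMIs. Free RNA was read from raw barcodes with 1 to 50 UMIs.

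The alternatives set beforehand were no or a stricter barcode filter (1000 genes, 5% mitochondrial UMIs), doublets kept, clustering resolutions of 0.5 and 2, joint clustering, class-restricted sums, trimmed mean of M values scaling (edgeR 4.0.16 in R 4.3.3), the mean of per-barcode CPM, totals without mitochondrial, ribosomal protein and globin genes, subtraction of 5% of free RNA, other CPM minimums, other G2M thresholds and other bounds for empty droplets. Alternatives chosen after seeing the data were the earlier naming versions, unnamed clusters under their best-scoring name, class contrasts within each library, empty droplets of 100 to 500 UMIs, and class-restricted sums without the cluster led by markers of another class. A test planned for Dspp in epithelial barcodes was set aside before it was run, in favour of tests on Ambn. The test of evenly spread globin replaced a ratio of the globin level to other barcodes, whose outcome was fixed because the cluster was chosen by its globin. The test for doublets among epithelial-like barcodes of the mesenchyme library first used the mesenchymal markers, which had also named the classes, and was read against doublets. It was replaced by the summed level of transcription factors that had named no class, which at 20.1% fell between the bounds of 10% and 25%. Since Dlx5, also expressed in the epithelium library's epithelial-like barcodes at 131 CPM, took most of that sum, the same factors were then read gene by gene, a version chosen after the values were seen. Trajectories, RNA velocity and ligand and receptor pairing were not analysed here. Figures were drawn with matplotlib 3.10.9.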

Results

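Single-cell RNA sequencing was performed on the molars of newborn Krt14-RFP mice, which carry a red fluorescent reporter under a Krt14 sequence. The dental epithelium and the dental mesenchyme were separated under a microscope after enzyme digestion and captured as 2 droplet libraries, with 1 library per layer. The labels give the age as postnatal day 1, while the protocol text names day 7, 7 littermates and, in places, incisors. The epithelium library held 6031 deposited barcodes and 38904788 unique molecular identifiers (UMIs) of mouse genes, and the mesenchyme library held 6181 barcodes and 39460774 UMIs. After filtering, 5962 barcodes with a median of 5781.5 UMIs and 2078 genes were kept in the epithelium library, and 5861 barcodes with a median of 5888 UMIs and 2204 genes in the mesenchyme library. With 1 library per layer, no difference between the layers had a replicate check, and all intervals are 95% intervals that cover counting error only.

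The first comparison asked which genes differed between the dissected epithelium and mesenchyme of the molar. Enam and Amelx, which encode enamel matrix proteins, were the genes with the largest folds in the epithelium library, and Pcp4 and Plppr1 those with the largest folds in the mesenchyme library, among genes with at least 50 CPM, UMIs scaled to the library total, in the higher library. Enam (ENSMUSG00000029286.12) measured 426 CPM in the epithelium library and 14.95 CPM in the mesenchyme library, a 28.5-fold ratio with an exact interval from 26.2 to 31.1. Amelx (ENSMUSG00000031354.16) measured 6642 CPM and 423 CPM, a 15.7-fold ratio with an interval from 15.4 to 15.9. The enamel protease gene Mmp20 was 6.94-fold higher in the epithelium library, at 138 CPM against 19.9 CPM. Krt14 (ENSMUSG00000045545.8), whose sequence drives the reporter, measured 1546 CPM in the epithelium library and 480.5 CPM in the mesenchyme library, a 3.22-fold ratio with an interval from 3.16 to 3.27.

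The other genes of the 12 largest folds in the epithelium library were Fxyd4, Tesc, Clu, Ctnna2, Tmem213, Dspp, Acpp, Stac3 and Sox21, with folds from 4.62 for Sox21 to 6.55 for Fxyd4. In the mesenchyme library, Pcp4 (ENSMUSG00000090223.1) measured 93.4 CPM against 1.55 CPM in the epithelium library, a 60.05-fold difference. Plppr1 was 35.3-fold, Crabp1 33.9-fold and Fgf3 29.6-fold higher in the mesenchyme library. The remaining genes of that group were Frzb, Omd, Fbn2, Emilin2, Lum, Chn1, Car2 and Olfml1, with folds from 13.2 for Olfml1 to 19.7 for Frzb. Lum was the most abundant of them, at 3031 CPM against 207 CPM. In all, 28 genes were at least 4-fold higher in the epithelium library and 251 in the mesenchyme library, counting genes with at least 10 CPM in the higher library. These counts rose to 375 and 683 when only epithelial-like barcodes of the epithelium library were set against mesenchymal-like barcodes of the mesenchyme library, and all 28 and 232 of the 251 genes were among them.

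Some of the 27 gene lists fixed before the data were examined separated the 2 libraries by tissue layer. Others did not, such as the dentin and bone matrix list, with a median log2 ratio of 0.04, and the Hedgehog pathway, with -0.12. The enamel matrix proteins and their proteases had a median log2 ratio of 2.69 over 7 measured genes, the hemidesmosome list 1.46 over 9, the keratins 1.42 over 13 and the epithelial junction genes 1.14 over 19. Each of these medians lay above all 10000 random lists matched on size and expression, as did those of the other genes of inherited enamel defects at 0.88 and the transcription factors of the dental epithelium at 0.75. The regulators of the epithelial to mesenchymal transition had a median log2 ratio of -2.45, the transcription factors of the dental mesenchyme -1.90, the secreted Wnt antagonists -1.86 and the interstitial collagens -1.19. Each of those 4 medians lay below all 10000 random lists.

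Among the genes behind these medians, Cdh1 was 3.60-fold, Trp63 3.02-fold and Krt5 2.68-fold higher in the epithelium library. Twist2 was 15.04-fold, Snai1 10.1-fold, Osr2 8.69-fold, Notum 7.88-fold, Barx1 7.81-fold and Msx1 6.17-fold higher in the mesenchyme library. The signal gene Shh was 2.65-fold higher in the epithelium library, while its receptor gene Ptch1 was 2.14-fold and its antagonist Hhip 4.29-fold higher in the mesenchyme library. Wnt3a was 3.35-fold and Fgf9 3.04-fold higher in the epithelium library, and Bmp2 was 3.98-fold and Wif1 5.03-fold higher in the mesenchyme library. The small leucine-rich proteoglycans had a median log2 ratio of -1.44, the FGF ligands and receptors -1.06, the matrix proteases and inhibitors -0.62 and the BMP and TGF-beta ligands and antagonists -0.32, and these lay at percentiles 0.020, 0.030, 0 and 1.24.

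Medians of the remaining lists lay within 0.5 of 0 on the log2 scale. The Notch pathway had 0.39 (percentile 99.9) between whole libraries. It had 0.32 (96.3) between epithelial-like barcodes of the epithelium library and mesenchymal-like barcodes of the mesenchyme library. Between the classes within the epithelium and the mesenchyme library it had -0.09 (33.2) and -0.58 (1.48). The Wnt ligands had 0.43 (99.8) between whole libraries and 1.07 (99.95) between epithelial-like and mesenchymal-like barcodes. Within the epithelium library they had 0 (44.5) and within the mesenchyme library 0.71 (99.75). The median of 0 was a value set by the rule for low counts and does not show equal levels. The ectodysplasin pathway had 0.47 (97.8) between whole libraries. The G2M genes had 0.05 (97.3) between whole libraries and 0.65 between epithelial-like and mesenchymal-like barcodes, 1.21 within the epithelium library and 0.94 within the mesenchyme library, the last 3 above all random lists. The dissociation stress genes had -0.38 (percentile 0.020), and the basement membrane core -0.38 (0.940). The S phase genes had -0.16 (3.08) between whole libraries but 0.39 (99.99) between epithelial-like and mesenchymal-like barcodes, and 1.27 and 0.83 within the epithelium and the mesenchyme library. The semaphorins, netrins and neurotrophic factors had -0.06 (percentile 48.1) between whole libraries and 0.05 (63.8) between epithelial-like and mesenchymal-like barcodes. Within the epithelium and the mesenchyme library they had -1.48 (0.080) and -1.31 (0.160). The genes of inherited tooth agenesis had 0.03 (77.2) and -0.22 (10.6) in the first 2 contrasts, and -0.36 (2.26) and -0.59 (0.420) within the libraries. The oxidative phosphorylation genes had 0.04 (73.5), the Hedgehog pathway -0.12 (25.45) and the Y-linked genes -0.21 (24.75). Xist measured 450.0 CPM in the epithelium library and 421 CPM in the mesenchyme library, and the Y-linked gene Eif2s3y 51.6 CPM and 54.7 CPM. The dentin and bone matrix genes had a median of 0.04 between whole libraries and -3.22 between epithelial-like and mesenchymal-like barcodes. The latter value is not independent of the naming, in which members such as Dmp1, Phex and Ibsp were subtype markers. In that list, Dspp was 5.13-fold higher in the epithelium library, whereas Smpd3 was 5.82-fold, Alpl 4.49-fold and Spp1 3.43-fold higher in the mesenchyme library. Within the epithelium library, however, Dspp was higher in mesenchymal-like than in epithelial-like barcodes, at 799 CPM against 277 CPM.

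**Figure D1:**
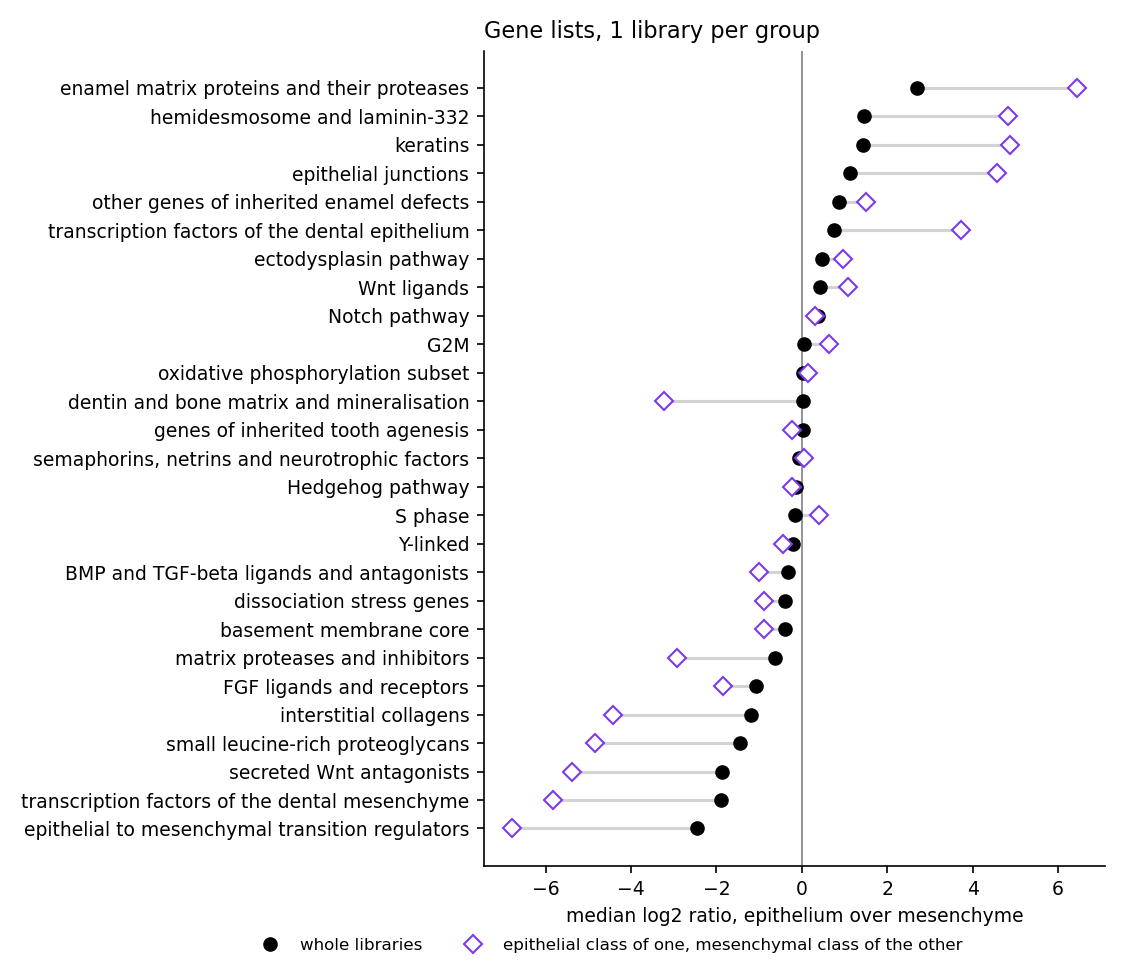
Median log2 ratio of the epithelium over the mesenchyme library (horizontal axis) for each of 27 gene lists (vertical axis), for whole libraries (filled circles) and for epithelial-like barcodes of the epithelium library against mesenchymal-like barcodes of the mesenchyme library (open diamonds), with 1 library per layer. The enamel matrix list moved from 2.69 to 6.44 and the dentin and bone matrix list from 0.04 to -3.22. Both lists held subtype markers that also counted in naming the classes, so these moves are not independent of the naming.

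The next comparison asked which cell classes each dissected layer contained. Epithelial-like barcodes, named from fixed markers such as Epcam, Krt5 and Trp63, made up 84.3% of the epithelium library (5024 of 5962, exact Clopper-Pearson interval 83.3% to 85.2%). Mesenchymal-like barcodes, named from markers such as Col1a1, Pdgfra and Prrx1, made up 62.2% of the mesenchyme library (3646 of 5861, 61.0% to 63.5%). Epithelial-like barcodes made up 34.2% of the mesenchyme library (2003 barcodes, 33.0% to 35.4%), and mesenchymal-like barcodes 9.06% of the epithelium library (540 barcodes, 8.34% to 9.81%). In the epithelium library, 30 endothelial-like, 30 perivascular-like, 24 macrophage-like and 11 skeletal muscle-like barcodes were found, and in the mesenchyme library 53 endothelial-like, 41 perivascular-like and 37 erythroid-like barcodes.

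The rule that turned the markers into names was revised after the clusters had been seen, and the epithelial share of the epithelium library was 81.6%, 73.1% and 84.3% under its 3 versions. The mesenchymal share of the mesenchyme library was 49.6%, 62.2% and 62.2%. Cluster 17 of the epithelium library (160 barcodes, globin genes in the lead) and cluster 10 of the mesenchyme library (269 barcodes, Ecel1 and Rprm in the lead) were epithelial-like, with 10 and 9 epithelial markers detected. Among their 10 leading genes over the rest of their own library, however, markers of another class outnumbered epithelial ones. The epithelial-like class is therefore given per library. Cluster 10 stays in the 34.2% of the mesenchyme library, for which no value without it is given. Clusters that met no name held 5.08% of the epithelium library, where a single cluster of 303 barcodes with 2372 CPM of Krt14 scored best as epithelial, and 1.38% of the mesenchyme library, where 81 barcodes carried myeloid genes such as Ccr1 and Ngp. Doublets were removed in the mesenchyme library only, since the caller marked 0.268% of the epithelium library and was taken not to have worked there.

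**Figure D2:**
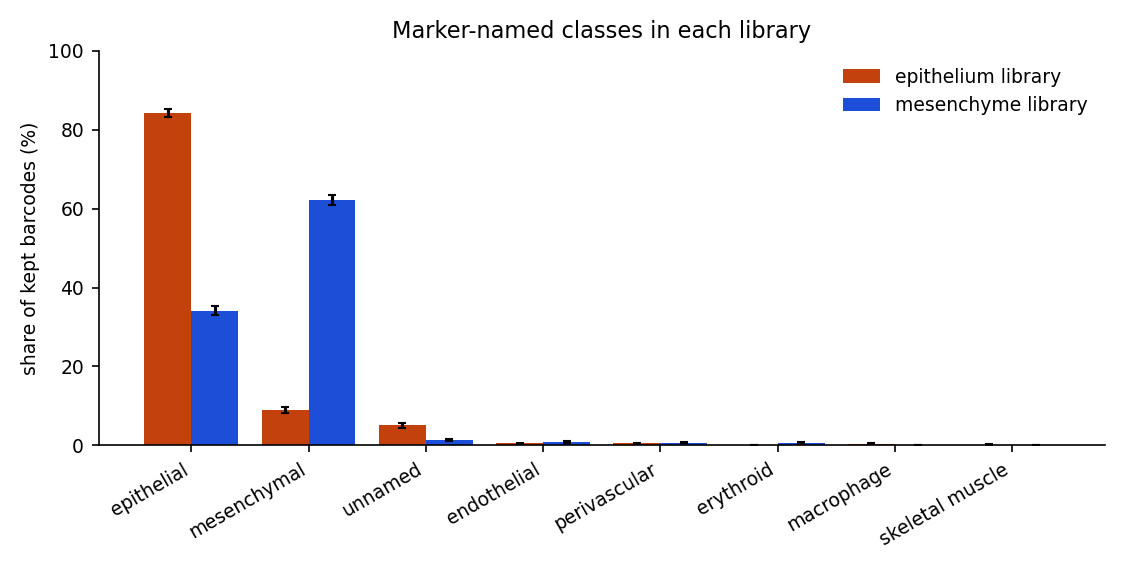
Share of kept barcodes in percent (vertical axis, from 0) for each marker-named class (horizontal axis) in the epithelium library and the mesenchyme library, with exact Clopper-Pearson 95% intervals as error bars. Epithelial-like barcodes made up 84.3% of one library and 34.2% of the other.

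The class-restricted comparison asked how the same genes differed once cells of the other layer were set aside. Enam measured 490.1 CPM in the epithelial-like barcodes of the epithelium library and 0.761 CPM in the mesenchymal-like barcodes of the mesenchyme library, a log2 ratio of 9.33. Amelx had a log2 ratio of 9.19, Fgf9 of 6.73 and Shh of 6.24. Frzb had a log2 ratio of -9.86, Twist2 of -9.25, Barx1 of -8.02 and Osr2 of -7.80, and none of these last genes was a marker used in naming. Enam, Amelx, Fgf9 and Shh were not broad class markers but were markers of epithelial subtypes. Subtype markers also counted among the leading genes when classes were named, so their ratios are not independent of the naming. Nor are the class contrasts of lists that held naming markers, such as the enamel matrix and the dentin and bone matrix lists. All 78 named genes that differed at least 2-fold between whole libraries kept their direction. Without cluster 17 of the epithelium library, 373 and 685 genes were at least 4-fold higher in the epithelial-like and mesenchymal-like barcodes.

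Within the epithelium library, subtypes of the enamel organ were named from fixed markers, and the genes given here were not among those markers and were chosen after their values were seen. The inner enamel epithelium-like subtype held 65.6% of the epithelial-like barcodes (3294 of 5024), the ameloblast-like subtype 8.40% (422) and the stratum intermedium-like subtype 7.17% (360), while 18.9% (948) met no subtype. The border between the first 2 is unsure, since a cluster of 673 barcodes named inner enamel epithelium-like had 10569 CPM of Amelx. Krt14 measured 5342 CPM in ameloblast-like barcodes (5256 to 5429), 1312 CPM in inner enamel epithelium-like barcodes and 682 CPM in stratum intermedium-like barcodes. Krt17 had the opposite order, with 535 CPM, 736 CPM and 6324 CPM. Hes1 measured 34.8 CPM, 84.9 CPM and 805 CPM in the same order of subtypes, and Vim 28.2 CPM, 86.0 CPM and 646 CPM. Wnt6 fell in that order, with 985 CPM, 336 CPM and 67.9 CPM, as did Satb1 with 742 CPM, 450.4 CPM and 147 CPM. The epithelial-like barcodes of the mesenchyme library showed the same orders for Krt14, Hes1, Vim, Wnt6 and Satb1, and Krt17 reached 6747 CPM in their stratum intermedium-like barcodes. The names cover unlike sets in the 2 libraries, however. The ameloblast-like cluster of the mesenchyme library (154 barcodes, 13894 CPM of Amelx) shared the leading genes Ctnna2 and Calb1 with the cluster of 673 barcodes. The joint cluster led by Ctnna2 and Calb1 was named inner enamel epithelium-like in the epithelium library and ameloblast-like in the mesenchyme library. The ameloblast lineage, counted as ameloblast-like and inner enamel epithelium-like barcodes together, made up 74.0% of the epithelial-like barcodes, and 56.3% when both libraries were clustered together.

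Within the mesenchyme library, the dental papilla-like subtype held 54.4% of the mesenchymal-like barcodes (1983 of 3646), the dental follicle-like subtype 11.1% (406) and the odontoblast-like subtype 3.40% (124, 2.84% to 4.04%), while 31.1% (1133) met no subtype. The odontoblast-like share depended on the clustering, from 0% at the lower resolution to 39.2% with both libraries clustered together. Dkk1 measured 899 CPM in odontoblast-like barcodes, 124 CPM in papilla-like barcodes and 34.6 CPM in follicle-like barcodes, and Bmp2 measured 372 CPM, 86.8 CPM and 16.1 CPM. Osr2 had the opposite order, with 15.8 CPM, 174 CPM and 401 CPM, and Ptch1 measured 246 CPM, 290.4 CPM and 424 CPM. These genes were also chosen after their values were seen and were not subtype markers. Of the 540 mesenchymal-like barcodes in the epithelium library, 305 were named odontoblast-like and 195 dental follicle-like. The odontoblast-like name is weak for part of the 305. Their cluster 18 was led by Omd, Plppr1 and Emilin2. It had 22.0 CPM of Dspp, less than the 112 CPM of the follicle-like cluster 15.

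Dspp, a marker used to name the odontoblast-like subtype, and Ambn, a marker of the ameloblast-like subtype, were followed across clusters, and both they and Col1a1 were singled out here after their values were seen. Dspp measured 1659 CPM (1611 to 1708) in the ameloblast-like barcodes and 1139 CPM (1095 to 1184) in the odontoblast-like barcodes of the epithelium library. The latter were cluster 14, with 198 of the 305 barcodes and 1734 CPM of Dspp, and cluster 18, with the rest and 22.0 CPM. In the ameloblast-like cluster with the most Dspp, at 1822 CPM, Col1a1 measured 62.2 CPM, against 19765 CPM in cluster 14 and 2228 CPM in cluster 18. Ambn measured 391 CPM in the epithelial-like barcodes of the epithelium library and 196 CPM in the mesenchymal-like barcodes of the mesenchyme library. In the mesenchyme library the epithelial-like barcodes had 67.8 CPM of Ambn, less than the mesenchymal-like ones, while Amelx measured 1161 CPM in the former and 13.2 CPM in the latter.

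**Figure D3:**
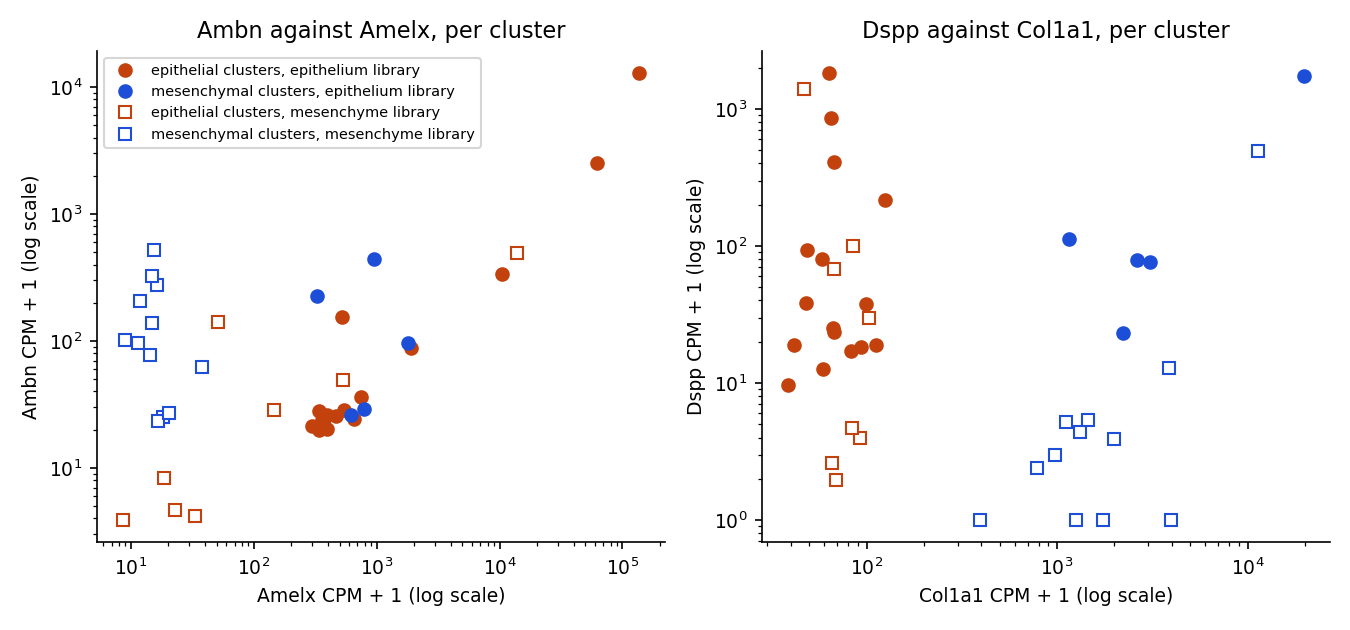
CPM plus 1 per cluster on log axes, Ambn (vertical) against Amelx (horizontal) on the left and Dspp (vertical) against Col1a1 (horizontal) on the right, with each point a cluster of the epithelial-like or mesenchymal-like class in the epithelium library (filled circles) or the mesenchyme library (open squares). Mesenchymal-like clusters of the mesenchyme library reached 518 CPM of Ambn at 14.4 CPM of Amelx, and Dspp reached 1822 CPM at 62.2 CPM of Col1a1.

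Expression of G2M genes was compared after each barcode was thinned to 3000 UMIs. At least 3 G2M UMIs were found in 74.6% of the epithelial-like barcodes of the epithelium library (73.3% to 75.9%) and in 61.4% of the mesenchymal-like barcodes of the mesenchyme library (59.7% to 63.0%), against 88.6% and 84.3% without thinning. With at least 5 UMIs these shares were 52.6% and 35.4%, so the level of the share was set by the threshold and is not a fraction of dividing cells. The ameloblast-like barcodes of the epithelium library had a share of 35.9%, against 79.0% in inner enamel epithelium-like, 71.5% in stratum intermedium-like and 77.6% in unnamed epithelial-like barcodes. The odontoblast-like barcodes of the mesenchyme library had a share of 41.7% (32.6% to 51.3%) and the mesenchymal-like barcodes of no named subtype 43.7% (40.7% to 46.7%), against 72.4% in papilla-like and 64.5% in follicle-like barcodes. The papilla-like subtype included clusters of 431 and 122 barcodes led by G2M genes such as Top2a and Cenpa. Part of its share therefore follows from the clustering. Ube2c measured 17.0 CPM in ameloblast-like and 310 CPM in inner enamel epithelium-like barcodes of the epithelium library, some of whose clusters were led by G2M genes such as Plk1 and Pttg1.

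The red reporter, recorded under a DsRed sequence and kept out of the clustering and naming, was compared with free RNA. DsRed measured 26316 CPM in the epithelial-like barcodes of the epithelium library and 25983 CPM in those of the mesenchyme library, against 3438 CPM and 269 CPM in the mesenchymal-like barcodes of each. At least 1 DsRed UMI was present in 62.2% of the mesenchymal-like barcodes of the mesenchyme library and in 98.9% of those of the epithelium library, at median depths of 5870.5 and 5264.5 UMIs. Droplets with 1 to 50 UMIs, taken as empty, held 22474 CPM of DsRed and 6023 CPM of Amelx in the epithelium library, and 7880.5 CPM and 395 CPM in the mesenchyme library. The libraries also differed in the depth of such droplets. Barcodes of 100 to 500 UMIs held 11339523 UMIs in the epithelium library and 1233419 in the mesenchyme library, and those of 1 to 100 UMIs 1325755 and 4116020. The shares of barcodes with a DsRed or Amelx UMI were not adjusted for this. In the mesenchymal-like barcodes of the epithelium library, 80% had an Amelx UMI, at 811 CPM, against 7.05% and 13.2 CPM in those of the mesenchyme library. The 10 epithelial markers measured 5837 CPM in empty droplets of the epithelium library, and the 10 mesenchymal markers 7777 CPM in those of the mesenchyme library.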

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

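All but 3 of the tests in this part were chosen after the results were seen. The test of the red reporter, the test for shared barcode sequences and the test of Ambn in barcodes without reporter were written before the values they measure were seen.

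Dspp and Sema3e differed between epithelial-like and mesenchymal-like barcodes in opposite directions in the 2 libraries. For Dspp the log2 ratio of epithelial-like over mesenchymal-like barcodes was -1.53 in the epithelium library and 2.32 in the mesenchyme library. For Sema3e it was -2.39 and 1.12. The difference between the libraries was not tested, since each had 1 sample. The mesenchymal-like barcodes differ in make-up between the libraries. In the joint clustering, which names them anew, the cluster led by the odontoblast markers Dmp1 and Phex held 38.8% of 500 in the epithelium library. In the mesenchyme library it held 5.64% of 3651.

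Transgene sequences other than DsRed, which no comparison used, had UMIs above the 3 that a count of 0 allows. The tdTom sequence had 369 UMIs in the epithelium library and 155 in the mesenchyme library, MCherry had 8 in the epithelium library, and the other transgene sequences together had 79 and 25. DsRed had 962627 and 367587 UMIs in the same libraries.

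In the 2003 epithelial-like barcodes of the mesenchyme library, DsRed was 96.7 times higher than in the mesenchymal-like barcodes (94.3 to 99.2). This cannot decide on free epithelial RNA, since a Krt14 sequence drives DsRed and Krt14 was a marker that named the class. Krt14 itself measured 1312 CPM in the epithelial-like and 16.6 CPM in the mesenchymal-like barcodes. Reads carried over from the other library are argued against by barcode sequences, of which 1.05% were shared with it, near the 0.818% that chance gives. Doublets bring every transcript of the mesenchymal cell and are argued against as the source by 13 mesenchymal transcription factors that named no class. Their median was 5.22% of their mesenchymal-like level, with Barx1 at 2.07% and Msx1 at 2.89%, and 7 of the 13 had intervals below 10%. Others stood high, with Dlx1 at 89.8%, Dlx5 at 82.3%, Gli1 at 77.2% and Dlx6 at 61.3%. The summed level was 20.1%, and the reading gene by gene was chosen after that sum was seen. Enamel organ left on the mesenchyme at the separation may be the source, but its test cannot decide. All 13 joint epithelial clusters, or 100%, also held at least 10 barcodes of the mesenchyme library. A class of this size made that likely from any source. The joint cluster led by Enam and Amelx held 1.90% of that library's epithelial-like barcodes and 7.92% of those of the epithelium library. A joint cluster led by Sfrp5 and Nppc held 12.5% and 4.62%. The labels name a single age and dissection, so no biological explanation was tested.

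Globin in a cluster of 160 epithelial-like barcodes of the epithelium library was weighed next. The median barcode of that cluster held 0.0055% globin, and 5 of its 160 barcodes held at least 10%. An even spread of free globin RNA is argued against, since that median stood at 0.252% of the cluster mean (0% to 0.487%). Red cell RNA may be the source. The ratio of Hbb-bt to Hbb-bs was 0.237, against 0.208 in 58 globin-dominated barcodes, a 1.14-fold difference (1.10 to 1.18). This ratio cannot tell free red cell RNA from red cells caught with another cell, since both would carry it. Chance pairing of red cells with any cell cannot be told apart, since the ratio of 21.7 between stratum intermedium and other barcodes rests on 5 globin-rich barcodes that all lie in the cluster chosen by its globin.

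Ambn in the mesenchymal-like barcodes of the mesenchyme library was weighed last. Free RNA from ameloblasts is argued against, since these barcodes had 14.9 Ambn UMIs per Amelx UMI and the ameloblast-like cluster of that library 0.0355, a 420.3-fold difference (383 to 462). Doublets with epithelial cells are argued against, since Ambn in the 1379 barcodes without a DsRed UMI stood at 102% of that in the 2267 barcodes with one (96.1% to 109%). Expression of Ambn by the mesenchyme, the layer the design names, may be what remains, as a hypothesis found and tested on the same data. Reads assigned to Ambn from other genes were not tested.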

How the results depend on the processing

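Of the 78 named genes that differed at least 2-fold, all kept their direction and at least 2-fold under the 8 alternatives set beforehand that were run on genes (no or a stricter filter, doublets kept, class-restricted sums, trimmed mean scaling, per-barcode means, totals without abundant families, free RNA subtracted), where the scalings' median shift over all genes was at most 0.07. Dspp reversed within the epithelium library, to a log2 ratio of -1.53, when its epithelial-like barcodes were set against its own mesenchymal-like barcodes, a contrast chosen after seeing the data. Cdca7 and Sema3d crossed 0 in that contrast, to 0.16 and -0.0457. With 71 and 108 UMIs in the mesenchymal-like barcodes, these 2 values lie too near 0 to give a direction. Lists with a median of at least 2-fold numbered 10, and 9 to 15 under these 8, against 19 and 17 within the epithelium and mesenchyme libraries. None of those 10 changed sign under these 8 or the 3 gene alternatives chosen later. Lists nearer 0 did, among them dentin and bone matrix (0.04 to -3.22) and S phase (-0.16 to 0.39) in class-restricted sums, and the Notch pathway (0.39 to -0.58) within the mesenchyme library. Part of the dentin and bone matrix list had served in naming the classes.

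The epithelial share of the epithelium library (84.3%) was 86.5% without a barcode filter, 87.2% with a stricter filter, 89.3% and 79.3% at resolutions of 0.5 and 2, and 89.4% with joint clustering. The ameloblast-lineage share (74.0%) was 69.9% without a filter, 58.2% at resolution 0.5 and 56.3% jointly. The odontoblast-lineage share (3.40%) was 5.21% without a filter, 0% at resolution 0.5 and 39.2% jointly. The mesenchymal share was 60.8% without a filter. Under the naming versions chosen after seeing the data, the first gave 81.6% epithelial, 49.6% mesenchymal, 68.6% ameloblast-lineage and 4.27% odontoblast-lineage, and the second 73.1% epithelial and 70.0% ameloblast-lineage. Unnamed clusters under their best-scoring name gave 89.3%, 79.6% ameloblast-lineage and 19.7% odontoblast-lineage. The cause was not tested.

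Barcodes with G2M UMIs (74.6% epithelial-like, 61.4% mesenchymal-like) were 88.6% and 84.3% without thinning, 86.3% and 79.1% with at least 2 UMIs, 52.6% and 35.4% with at least 5, and 72.9% and 55.5% under the first naming version. Lower thresholds and unthinned depth raise such a count by construction.

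Genes at least 4-fold higher (28 and 251) numbered 375 and 683 in class-restricted sums, 373 and 685 without the globin-led cluster, 244 and 735 within the epithelium library, 328 and 667 within the mesenchyme library, 287 and 1271 with no CPM minimum, and 13 and 86 at 50 CPM. Class sums leave out cells of the other layer, and a minimum leaves out genes. Under the other alternatives the counts were 27 to 34 and 225 to 294.

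Empty droplets of 1 to 100 UMIs held 5528 CPM of epithelial markers and 7372 CPM of mesenchymal markers in the matching libraries, those of 1 to 20 UMIs 8428 CPM of mesenchymal markers, and those of 100 to 500 UMIs 5577 and 8044 CPM. The cause was not tested. Of 904 values of named genes under the 8 alternatives, 813 stayed within 1.5-fold and 91 moved further without reversing. Depth limited the contrasts within the epithelium library, where the 540 mesenchymal-like barcodes gave genes of low level few UMIs. Epithelial RNA in those barcodes was a further limit. They had 3438 CPM of DsRed and 811 CPM of Amelx, against 269 and 13.2 CPM in those of the mesenchyme library. The enamel matrix list had a median log2 ratio of 1.82 within the epithelium library and 4.96 within the mesenchyme library. The subtraction of 5% of free RNA was run on whole libraries only. No paired analysis was possible because no test was run with 1 library per group.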

Other observations

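The mesenchymal-like clusters of the mesenchyme library differed in Ambn. The highest was a cluster of 451 barcodes with 518 CPM, and the odontoblast-like cluster had 321 CPM, while the large dental follicle-like cluster of 343 barcodes had 24.3 CPM. In the epithelium library, Ambn reached 12890 CPM in an ameloblast-like cluster of 43 barcodes, where Amelx measured 136396 CPM and Dspp 405 CPM. The ameloblast-like cluster of 379 barcodes had 2502 CPM of Ambn and 1822 CPM of Dspp.

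The unnamed cluster of 303 barcodes in the epithelium library had 46298 CPM of DsRed and 1013 CPM of Stmn2, with Uchl1 and Hbegf among its leading genes. An epithelial-like cluster of 269 barcodes in the mesenchyme library had 46744 CPM of DsRed and 643 CPM of Stmn2, with Ecel1 and Rprm in the lead.

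Features other than mouse genes took 2.42% of all UMIs in the epithelium library and 0.923% in the mesenchyme library, nearly all of them DsRed. The spike-in sequences had 0 UMIs in both libraries. Hbb-bs measured 609 CPM in the epithelium library and 2248 CPM in the mesenchyme library.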
